A study of Exaiptasia diaphana with 16 samples.

How the data were processed

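Larvae of the sea anemone Exaiptasia diaphana (Aiptasia), from a cross of the strains CC7 and F003, were kept without algae or were infected with the dinoflagellate alga Breviolum minutum, per the labels' protocols. The outer tissue layer was removed enzymatically, the inner layer (endoderm) was macerated, and single endodermal cells were picked with a microcapillary and pooled. Full-length cDNA was made from polyadenylated RNA of each pool by Smart-seq2, a protocol for very small amounts of RNA without molecular identifiers, and sequenced as paired ends. The 16 libraries form 3 groups, taken from the sample labels: aposymbiotic (alga-free) cells of aposymbiotic larvae (n = 5), aposymbiotic cells of symbiotic larvae (n = 5) and alga-containing cells of symbiotic larvae, called symbiotic cells (n = 6). The labels do not say that the pools came from separate spawnings or cultures, so the p-values measure the spread between these samples, which may be partly technical.

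The authors deposited 1 table with a value for each of 27334 RefSeq transcripts in each of the 16 libraries. Its deposited values are an expression signal scaled by the trimmed mean of M values (TMM), per the file headers. They are linear, fractional and never negative, and their column sums range from 688152 to 1737937. They are therefore neither counts nor plain TPM values, and the read depth of the libraries is unknown. The submitters' processing notes name HISAT2 2.1.0, Salmon 0.10.2 and DESeq2 without saying what each was used for. The genome build and the annotation release were not given in the sources used here. The analysis had been planned for values of the TPM kind, and the same test was used for this signal; a count model was not run. An exact 0 in such a table can be a failed estimate, so transcripts are described as listed at 0, and no fold of a single transcript is given against a group listed at 0. Medians of folds over all tested transcripts do include such transcripts, so their size depends on the pseudocount. Medians over sets of called transcripts leave out those listed at 0 in every library of a group, but many that remain are at 0 in most of its libraries, so these medians depend on the pseudocount too.

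Identifiers were looked up in the RefSeq gene table of the assembly Aiptasia genome 1.1. Of the 27334 transcripts, 2683 matched with their version and 21267 when the version was ignored, belonging to 18293 genes. Apart from 1 gene, all matched genes carry only a LOC number as a symbol. None of these symbols matched any of the 24 gene lists and cell type marker lists that had been fixed (0 matches), so the list tests were not run, and no function is stated for any transcript. No coordinates were used.

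Transcripts with a value of at least 1 in at least 5 libraries were tested (8975). Values were transformed as log2(value + 1), and fold changes are on that scale, which understates changes of low transcripts. The main test was limma 3.58.1 (R 4.3.3, statmod 1.5.0) with an intensity trend and robust variance moderation, fitted to all 16 libraries with 3 groups and no covariate. Adjusted p-values are Benjamini-Hochberg values over the transcripts tested, two-sided, with a threshold of 0.05. The 2 infection times were compared in the 11 libraries of symbiotic larvae with 4 groups of cell state by time. Transcripts per library, cells per pool and shares of signal were compared by exact two-sided permutation tests of the difference in means, adjusted over the 3 comparisons of each measure. Figures were drawn with matplotlib 3.10.9.

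Without descriptive gene names, the rule fixed for naming transcripts allows at most 2 higher and 2 lower ones per comparison, by smallest p. Where a direction held 5 or fewer calls, the rest of them were named after their values had been seen. The groups, tests, naming rule and first set of alternatives were chosen before the data were examined. Those alternatives were other pseudocounts, low-value filters, scalings and variance models, the compared groups alone, weights per library, the replicate number as a block, cell number or infection time as covariates, each infection time alone, a rank test, and leaving out single libraries. Added after the data were seen were an analysis with the same number of transcripts kept in each library, a common floor of 100, the number of transcripts detected as a covariate, and leaving out together the libraries with the most and the fewest transcripts.

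The limma step was tested on simulated data in which 200 of 8975 transcripts were changed at the observed spread. For symbiotic cells against aposymbiotic cells of symbiotic larvae, 7.46% of changes of 3 log2 units, 29.9% of changes of 5 and 60.6% of changes of 7 were recovered, with 5 false calls over all sizes. For symbiotic cells against cells of aposymbiotic larvae the recovered shares were 5.97%, 25.4% and 72.7%, with 2 false calls. For the 2 aposymbiotic groups they were 1.49%, 17.9% and 48.5%, with 5 false calls. The simulation drew independent normal noise for each transcript and balanced changes up and down, in transcripts with enough signal for both. It held no difference in detection between groups and no noise shared by transcripts of a library. Its few false calls therefore do not give the error rate in the real data.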

Results

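Gene expression was measured in hand-picked pools of endodermal cells to compare cells that hold algae with cells that do not. Pools of cells from aposymbiotic larvae held 17.6 ± 2.51 cells (SD, n = 5), those of aposymbiotic cells from symbiotic larvae 17.8 ± 3.03 cells (SD, n = 5) and those of symbiotic cells 9.83 ± 3.31 cells (SD, n = 6). Infection had lasted 24 h or 48 h. All pools were taken at 7 days after fertilisation, except symbiotic cell replicate 4, which is labelled 8 days although its infection began at day 5 and lasted 48 h. Per library, 38.6% to 62.8% of the signal lay in the 100 most abundant transcripts. The highest mean over the 16 libraries was that of XM_021060755.1 (LOC110253803), with medians of 40400 in cells of aposymbiotic larvae, 47860 in aposymbiotic cells of symbiotic larvae and 32550 in symbiotic cells. Next was the long non-coding XR_002334655.1 (LOC110239353), with medians of 57910, 46960 and 31150. XM_021060755.1 and XR_002334655.1 are described for their level, not for a difference.

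Symbiotic cell libraries contained fewer detected transcripts than libraries of either aposymbiotic group. Transcripts with a value of at least 1 numbered 2985 ± 1050 (SD, n = 6) in symbiotic cells, 9420 ± 3230 (SD, n = 5) in aposymbiotic cells of symbiotic larvae and 6813 ± 2050 (SD, n = 5) in cells of aposymbiotic larvae. The difference was -6435 against the former and -3827 against the latter, each with an exact permutation p of 0.00216 (adjusted p = 0.00324), and no symbiotic cell library overlapped either group. The aposymbiotic groups differed by 2607, which did not pass (exact permutation p = 0.151). Within each infection time the order was kept: at 24 h, symbiotic cells ranged from 1458 to 4349 and aposymbiotic cells from 7142 to 9114, and at 48 h from 2572 to 3782 and from 7391 to 15019. The 100 most abundant transcripts took 54.7% ± 6.04 (SD, n = 6) of the signal in symbiotic cells, 43.2% ± 2.85 (SD, n = 5) in aposymbiotic cells of symbiotic larvae (exact permutation p = 0.0108, adjusted 0.0324) and 45.2% ± 5.41 (SD, n = 5) in cells of aposymbiotic larvae (exact permutation p = 0.0281, adjusted 0.0422). The share of signal in non-coding transcripts was 10.9% ± 2.07, 10.4% ± 0.955 and 11.9% ± 1.60 (SD) in the same order, with no difference passing. Symbiotic cell pools also held fewer cells than each other group (exact permutation p = 0.00866, adjusted 0.013), and only 1 of the 6, with 16 cells, was as large as the smallest pool of aposymbiotic cells from symbiotic larvae. Within symbiotic cells, the relation of cells per pool to transcripts detected had a Pearson r of 0.658 (exact permutation p = 0.153) and a Spearman rho of 0.638 (p = 0.194, n = 6), with r = 0.927 when the 2 pools farthest from the median were left out. Neither relation passed the test.

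**Figure D1:**
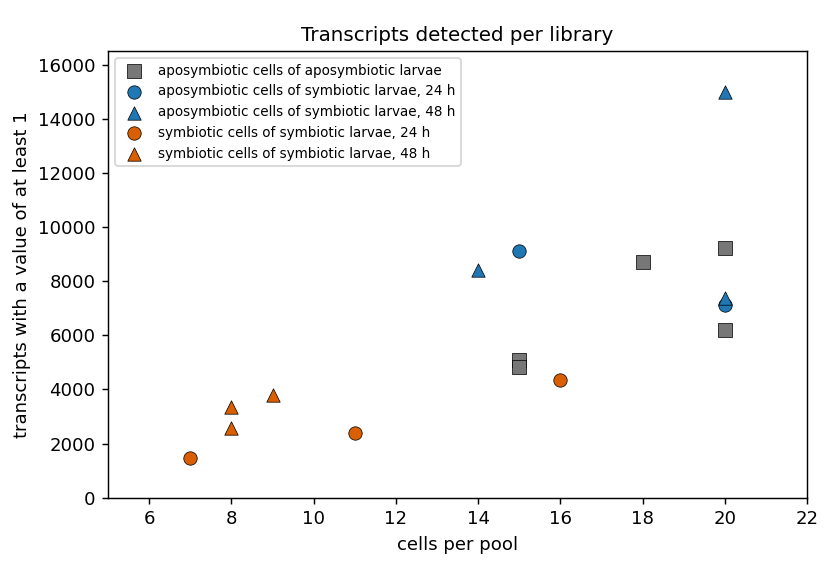
Number of transcripts with a value of at least 1 in each library, on the vertical axis, against the number of cells in its pool. Each point is 1 library, coloured by group and shaped by infection time; the 6 symbiotic cell libraries (1458 to 4349 transcripts) lie below all 10 others (4839 to 15019).

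The first comparison set symbiotic cells against alga-free cells of larvae that were also infected. The most clearly higher transcript in symbiotic cells was XM_021059980.1 (LOC110253103), with a median of 19690 (range 9457 to 170600) against 3777 (1711 to 4623), a log2 fold of 3.28 ± 0.637 (SE; limma, adjusted p = 0.00396). It was the most abundant transcript of symbiotic cell replicates 1 and 2, where it took 14.2% and 6.53% of the signal. XM_021048621.1 (LOC110242610) had medians of 6786 and 1115, a log2 fold of 3.05 ± 0.804 (SE; limma, adjusted p = 0.0189). XM_021061100.1 (LOC110254138) had medians of 2137 and 253.9, a log2 fold of 3.38 ± 0.957 (SE; limma, adjusted p = 0.0244). XM_021059882.1 (LOC110253024) had medians of 1315 and 217.2, a log2 fold of 3.15 ± 0.987 (SE; limma, adjusted p = 0.0342). XM_021044193.1, which matched no gene, lay between 5.34 and 225.2 in symbiotic cells and was listed at 0 in 4 of the 5 aposymbiotic libraries, with 0.064 in the remaining one (limma, adjusted p = 0.0166). For all 5, each of the 6 symbiotic cell libraries lay above each of the 5 aposymbiotic libraries. By exact permutation of the values, a test chosen later, unadjusted p was 0.039 for XM_021059980.1 and 0.0195 for XM_021048621.1. The same exact permutation test did not reach 0.05 for XM_021061100.1 (p = 0.0671), XM_021059882.1 (p = 0.0714) and XM_021044193.1 (p = 0.0628).

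In the same comparison 1168 transcripts were lower in symbiotic cells, so that 1173 of 8975 changed (limma). The lower ones with the smallest p were XM_021036897.1, which matched no gene and ranged from 141.7 to 295.9 in aposymbiotic cells of symbiotic larvae, and XM_021049841.1 (LOC110243713), which ranged from 180.1 to 522.5. Both were listed at 0 in all 6 symbiotic cell libraries, and each had an adjusted p of 0.00175. Of the 1168, 404 were listed at 0 in all symbiotic cell libraries and 792 in at least 5 of them, while 6 were listed at 0 in none. The lower set held 1134 coding and 34 non-coding transcripts, a share of non-coding ones that did not differ from that of the other tested transcripts (Fisher's exact p = 0.925). The shift was general among the tested transcripts: 92.8% had a fold below 0, and 3300 had an unadjusted p under 0.05 (limma). The filter favours such folds. A transcript could pass it in 5 aposymbiotic libraries alone, and these had more transcripts detected than the symbiotic cell libraries. The median log2 fold was -2.16, but its size depended on the settings. It was -3.72 with a pseudocount of 0.1, -1.19 with a pseudocount of 5 and -0.84 without a filter on low values. With median-of-ratios scaling it was -1.73. Non-overlapping groups were found for 6.53% of tested transcripts, against 0.433% by chance. That chance share holds for groups alike in detection, but detection did not overlap between these groups. The excess therefore cannot be told apart from lower detection.

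These counts moved with the treatment of detection and cell number, which differ between the groups. With cell number as a covariate, or with the number of transcripts detected (a covariate added later), 0 transcripts passed (limma), while errors widened. In these fits 1108 and 534 had an unadjusted p under 0.05 (limma), where 449 would be so by chance. XM_021059980.1 had log2 folds of 4.25 ± 0.922 and 3.12 ± 1.11 (SE) in these fits, and the 764 lower transcripts not listed at 0 in all symbiotic cell libraries medians of -4.55 and -3.34, against -4.95 without a covariate. The median SE of these 764 was 2.39 and 2.74, against 1.48. As 388 of the 764 were listed at 0 in 5 of the 6 libraries, the medians depend on the pseudocount: with 0.1 they were -6.84 and -4.86, against -7.36 without a covariate, and with 5 they were -2.94 and -2.24, against -3.29. With quantile normalisation, which removes most of the median shift (median log2 fold -0.04), 4 were higher and 23 lower. Within infection times, 24 h libraries alone gave 0 higher and 1183 lower transcripts, and 48 h libraries alone 1 higher and 1032 lower; XM_021059980.1 had a log2 fold of 4.44 at 24 h (adjusted p = 0.0995) and of 2.20 at 48 h (adjusted p = 0.0289). XM_021059882.1 also lost its call without any of replicates 3, 4 and 5 of the aposymbiotic cells, and XM_021061100.1 and XM_021044193.1 without replicate 3. The total of 1173 fell to 241 without that replicate 3, to 645 without replicate 4 of the same group, and to 457, 767 and 587 without symbiotic cell replicates 2, 3 and 4.

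**Figure D2:**
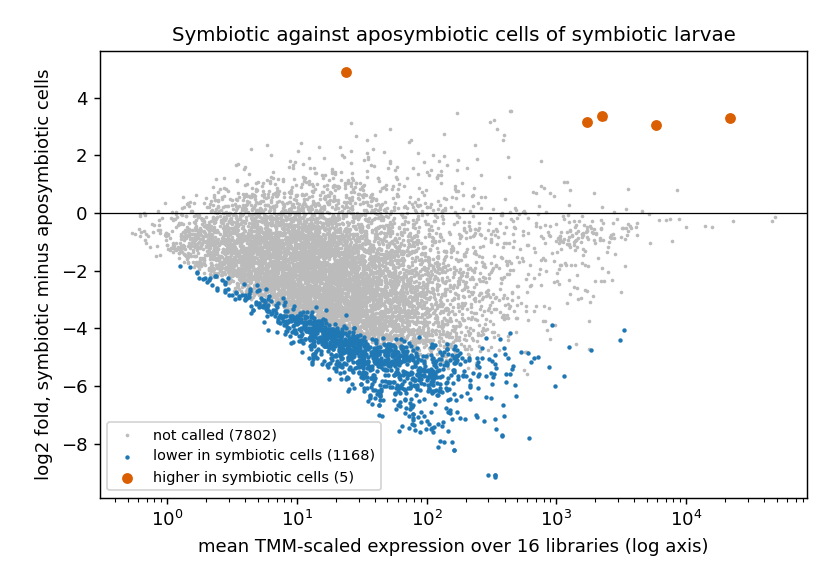
Log2 fold of symbiotic against aposymbiotic cells of symbiotic larvae, on the vertical axis, against the mean TMM-scaled expression over 16 libraries on a log axis. Each point is 1 of 8975 tested transcripts; most lie below 0, the 1168 called lower span the whole range of low to middle expression, and 4 of the 5 called higher are among the abundant transcripts.

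The second comparison set symbiotic cells against cells of larvae that never met the alga. XM_021052404.1 (LOC110246096) was the only transcript called higher. It ranged from 47.4 to 3387 in symbiotic cells and was listed at 0 in 4 of the 5 libraries of aposymbiotic larvae, with 46.6 in replicate 3 (limma, adjusted p = 0.0327). In aposymbiotic cells of symbiotic larvae its median was 59.2, with a range of 0 to 505.8, and neither comparison with that group passed. The lower transcripts with the smallest p were XM_021060756.1 (LOC110253804), at most 0.249 in symbiotic cells and 186.5 to 547.9 in aposymbiotic larvae, and XM_021049841.1, listed at 0 in all symbiotic cells and 103.6 to 355.4 in aposymbiotic larvae. Both had an adjusted p of 0.0127 (limma).

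In total 101 transcripts changed, 1 higher and 100 lower, of which 32 were listed at 0 in all symbiotic cell libraries; 1824 had an unadjusted p under 0.05 and the median log2 fold was -1.46. The 4 abundant transcripts that were higher than in aposymbiotic cells of symbiotic larvae did not pass here. Their log2 folds were 1.71 ± 0.637 for XM_021059980.1 (adjusted p = 0.139), 1.34 ± 0.804 for XM_021048621.1 (adjusted p = 0.33), 1.98 ± 0.957 for XM_021061100.1 (adjusted p = 0.235) and 1.73 ± 0.987 for XM_021059882.1 (adjusted p = 0.309), each with its SE from limma. By exact permutation of the values, unadjusted p was 0.11, 0.203, 0.121 and 0.177 in the same order. The call of XM_021052404.1 was lost under 15 of 26 other settings, among them the 2 compared groups alone, under which 0 transcripts passed. Quantile normalisation also left 0, as did cell number or transcripts detected as a covariate. Errors widened with these covariates: the median SE of the 68 lower transcripts not listed at 0 in all symbiotic cell libraries was 2.36 and 2.23, against 1.48 without. Their median log2 folds were -6.25 and -5.28, against -6.11. Single libraries moved the total to 9 without replicate 3 of aposymbiotic larvae, 27 without their replicate 4, 50 without their replicate 1, and 21, 22, 36 and 47 without symbiotic cell replicates 1, 2, 3 and 4.

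**Figure D3:**
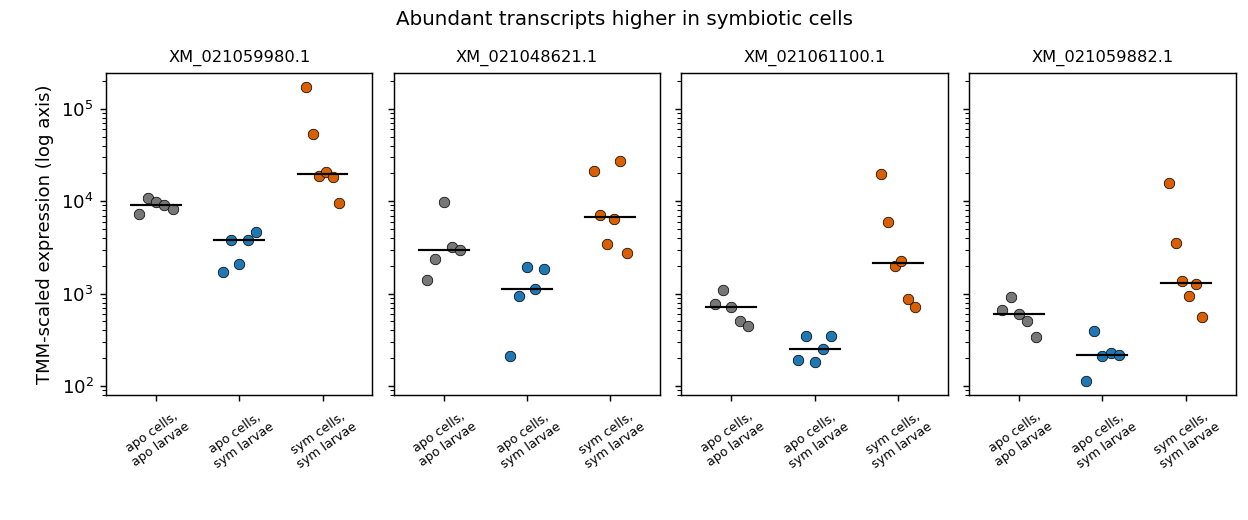
TMM-scaled expression, on a log axis, of the 4 abundant transcripts called higher in symbiotic than in aposymbiotic cells of symbiotic larvae (apo, aposymbiotic; sym, symbiotic). Points are libraries and horizontal lines medians; the 6 symbiotic cell libraries lie above the 5 aposymbiotic libraries of symbiotic larvae in each panel, and the libraries of aposymbiotic larvae lie between or overlap them.

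The third comparison asked whether alga-free cells of infected larvae differ from cells of uninfected larvae. XM_021041964.1 (LOC110236442) ranged from 47.97 to 209.5 in aposymbiotic cells of symbiotic larvae and was listed at 0 in all 5 libraries of aposymbiotic larvae. XM_021036897.1 ranged from 141.7 to 295.9 and was listed at 0 in 4 of those 5 libraries, with 2.27 in replicate 1. Both had an adjusted p of 0.009 (limma) and were listed at 0 in all 6 symbiotic cell libraries. They belong to 8 transcripts that were higher, with values of 5.48 to 295.9 in aposymbiotic cells of symbiotic larvae and at most 2.27 in aposymbiotic larvae. In symbiotic cells 45 of their 48 values were 0, and all 8 were among the transcripts lower in symbiotic cells than in aposymbiotic cells of symbiotic larvae. None was lower (0 transcripts; 716 in both directions had an unadjusted p under 0.05 in limma). The 4 abundant transcripts lay lower in aposymbiotic cells of symbiotic larvae than in aposymbiotic larvae without passing in the fit of all 3 groups, at log2 folds of -1.58 ± 0.665 for XM_021059980.1, -1.72 ± 0.840 for XM_021048621.1, -1.40 ± 0.999 for XM_021061100.1 and -1.42 ± 1.03 for XM_021059882.1 (SE; limma, adjusted p from 0.492 to 0.835). In the fit of the 2 aposymbiotic groups alone XM_021059980.1 passed, with an SE of 0.272 (limma, adjusted p = 0.0124), and the other three did not (adjusted p from 0.484 to 0.651). By exact permutation of the values, a test chosen later, p was 0.00794, 0.0317, 0.00794 and 0.0159 in the same order (adjusted over the 4 transcripts 0.0159, 0.0317, 0.0159 and 0.0212). XM_021059980.1 (1711 to 4623 against 7224 to 10880) and XM_021061100.1 (181.7 to 345 against 447 to 1083) did not overlap between these groups. The 4 had been picked by a comparison with the same aposymbiotic libraries, which favours low values there. The count of 8 fell to 0 without replicate 3 of aposymbiotic larvae, to 2 without their replicate 5 and to 3 without their replicate 4 or without replicate 3 of the aposymbiotic cells of symbiotic larvae. It rose to 13 without replicate 2 or 5 of the latter and to 19 without their replicate 1, and a fit of the 2 groups alone called none of the 8.

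Both comparisons of symbiotic cells use the same 6 libraries. Among their lower transcripts, 70 were shared, XM_021049841.1 among them, where independent lists would share 13. The median over 100 simulations of unchanged groups was 0 (highest 1), but these had at most 2 and 1 calls in the comparisons, so they could share hardly any. No higher transcript was shared (0). The fold changes correlated across transcripts, which are not independent replicates, with r = 0.601 (simulated 0.452) and a covariance of 1.63 (simulated 0.948, difference 0.685). With the symbiotic cell libraries divided between the comparisons in 20 ways, 5 to 12 lower transcripts were shared (median 9), from lists of 22 to 673 and of 8 to 296, where independent lists would share 0.421 to 1.36. The median r was then 0.209 and the median covariance 0.75. Both fits still took the spread from all aposymbiotic libraries. The divided lists were thus not independent either, and the independent count is only a rough reference.

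The labels also allow 48 h to be compared with 24 h of infection within symbiotic cells (n = 3 each). The 24 h pools were infected from day 6 and the 48 h pools from day 5. Infection time therefore cannot be told apart from age at infection. The pool labelled 8 days is among the 48 h pools. XM_021054791.1 (LOC110248279) and XM_021051173.1 (LOC110244940) were listed at 0 in all 24 h libraries and ranged from 188.2 to 593.7 and from 162.2 to 193.9 at 48 h. XM_021047283.1 (LOC110241430) ranged from 61.6 to 654.7 at 24 h and was listed at 0 in all 48 h libraries, and XM_021038529.1 (LOC110233259) ranged from 308.2 to 535.1 at 24 h and from 0 to 14.5 at 48 h. None of the 4 passed (limma, adjusted p from 0.632 to 0.811). The test called 0 transcripts, with 369 at an unadjusted p under 0.05 where 449 would be so by chance, and the interaction of time with cell state called 0 (500 unadjusted). Within aposymbiotic cells of symbiotic larvae the same contrast called 0 (871 unadjusted). For the higher transcripts of symbiotic cells, the change from 24 h to 48 h was -1.85 ± 0.754 log2 units for XM_021059980.1, -2.45 ± 1.04 for XM_021061100.1, -2.27 ± 1.10 for XM_021059882.1, -2.13 ± 1.56 for XM_021044193.1 and -0.04 ± 0.991 for XM_021048621.1 (SE; limma), none of which passed (adjusted p = 0.945 for the first 4 and 1 for the last). Without symbiotic cell replicate 3, the contrast called 5 transcripts.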

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

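The tests of explanations below, the counts over other splits of the samples included, were written down after the results were seen. Of 29 groups of libraries examined for a sample far from the others, 12 had one. Chance gives about 1 in 20 for normal values, but these are linear and skewed, so no excess over chance is shown. The ratio given is the gap to the nearest library divided by the range of the group, and it is fixed at 1 in the 3 groups where all other libraries are listed at 0.

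In aposymbiotic cells of symbiotic larvae, replicate 3 had 15019 transcripts detected and the next library 9114 (ratio 0.75). Symbiotic cell replicate 1 stood above the rest for XM_021059980.1 (170600 against 52890, ratio 0.73), XM_021061100.1 (19600 against 5982, ratio 0.721), XM_021059882.1 (15600 against 3535, ratio 0.802) and XM_021044193.1 (225.2 against 69.3, ratio 0.709). XM_021044193.1 was above 0 in aposymbiotic cells of symbiotic larvae in replicate 2 only, at 0.064 (ratio 1). For XM_021048621.1, replicate 3 of aposymbiotic larvae lay at 9902 and the next at 3157 (ratio 0.794). XM_021036897.1 in aposymbiotic larvae was above 0 in replicate 1 only, at 2.27 (ratio 1), and XM_021052404.1 in replicate 3 only, at 46.6 (ratio 1). In symbiotic cells XM_021052404.1 reached 3387 in replicate 4 and 1004 in the next library (ratio 0.714). For XM_021060756.1, replicate 4 of aposymbiotic larvae lay at 547.9 above 290.9 (ratio 0.711), and symbiotic cell replicate 4 at 0.249 above 0.078 (ratio 0.687).

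The broad decrease in symbiotic cells came out as 1173 changed transcripts against a highest other count of 331. Of 100 splits drawn from 462 possible ones, only the real one gave as many, so a random division of these pools seldom does. This cannot exclude chance between spawnings or cultures, which the labels do not separate. Nor can it separate cell state from detection, which did not overlap between the groups. Against aposymbiotic larvae 1 of 100 splits, the real one, gave as many (101, highest other 67), but the fit of those 2 groups alone called 0. Fewer transcripts detected per library and fewer cells per pool stay open as explanations of the 1168 lower transcripts, beside a lower RNA content or a changed expression of cells with algae, which was not tested. When each library kept 1458 transcripts and was scaled to the last one kept, 0 of the 296 that could be tested were still lower, the median log2 fold of the 256 of them not listed at 0 in all symbiotic cell libraries moving from -5.55 to -0.49 (interquartile range -0.91 to -0.17); but setting them to 0 in all symbiotic cell libraries would have left only 18, so this test could hardly have come out otherwise. Cell number cannot be told apart from the group, since 1 symbiotic cell pool was as large as the smallest pool of the other group. With either measure as a covariate 0 calls were left, but this does not show it to be the cause, as errors widened. The median log2 fold of the 764 not listed at 0 in all symbiotic cell libraries was -4.95 (median SE 1.48) without a covariate. It was -4.55 (2.39) with cell number and -3.34 (2.74) with transcripts detected. At pseudocounts of 0.1 and 5 these medians were -7.36, -6.84 and -4.86, and -3.29, -2.94 and -2.24. The 764 were picked for low folds in these same libraries, and many were at 0 in most symbiotic cell libraries. Their folds therefore cannot show how much either measure accounts for. Over all tested transcripts the median log2 fold moved from -2.16 to -1.81 with cell number and to -0.43 with transcripts detected.

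The 4 abundant transcripts higher in symbiotic cells went against the general shift. A signal spread over fewer transcripts would raise abundant transcripts together. The median log2 fold of the other 96 of the 100 most abundant was -0.719 (interquartile range -1.27 to -0.43). The sign of this median decides nothing, as it depends on the scaling: median-of-ratios scaling moved XM_021059980.1 from 3.28 to 3.94. A scaling factor moves all abundant transcripts of a library alike. It alone would not part the 4 from the 96, but the 4 were picked for high folds in this same comparison. Some gap to the 96 was therefore fixed in advance, so it does not decide against such a spread. Among the 96, XM_021059454.1, singled out after its values were seen, had 3.28 without passing (limma, adjusted p = 0.246). Reads from the alga cannot be told apart from host expression: all 4 transcripts reached 100 in every library of larvae without algae, yet algal reads could add to that level, since the symbiotic medians lie above the highest of those libraries for 3 of the 4. Reads shared between similar transcripts also stay open, since XM_021059980.1, XM_021061100.1 and XM_021059882.1 kept nearly fixed ratios (smallest SD of a log2 ratio over 16 libraries 0.406, with 1.38% of 4560 pairs of other abundant transcripts tighter), as common regulation would give too. Low values in the aposymbiotic cells of symbiotic larvae also enter these folds. Against aposymbiotic larvae the log2 folds of the 4 were 1.34 to 1.98, none passing, and between the aposymbiotic groups -1.72 to -1.40. The choice of the 4 favours low values there, so a lower level in alga-free cells of infected larvae stays open too. A response to the alga within the host cell remains a hypothesis that these tests leave open.

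For the 8 transcripts higher in aposymbiotic cells of symbiotic larvae than of aposymbiotic larvae, 7 of 100 splits of the samples gave as many, with a highest other count of 53, so chance cannot be excluded. What gave the larger counts was not tested. More transcripts detected in these libraries could in part give such a set: 12 transcripts reached 10 in all 5 of them and in no other, and 9 other sets among all 4368 of 5 libraries gave as many (highest 18), each with replicate 3, the library with the most transcripts. At thresholds of 1, 5 and 20, 30, 16 and 4 other sets did; of the 18 sets with more transcripts detected in total, 15, 9, 7 and 3 did at 1, 5, 10 and 20, while most of the 4368 hold symbiotic cell libraries with few transcripts. With transcripts detected as a covariate, which moved the median log2 fold of all transcripts from 0.59 to 0.11, the folds of the 8 stayed between 0.936 and 1.04 of their size (median of the 6 not listed at 0 in all aposymbiotic larvae 6.24 before and 6.13 after, median SE of the 8 1.24 and 1.35), but only 2 passed (adjusted p = 0.0427), as errors widened and the other adjusted p rose up to 0.158. The stable folds decide nothing, as the 8 were chosen for low values outside this group. In symbiotic cells 45 of their 48 values were 0, and in aposymbiotic larvae they were at most 2.27. Such flat values draw the fitted slope toward 0, so the covariate could hardly have moved the folds. Detection therefore cannot be told apart from an effect of the infection on alga-free cells, which was not separately tested.

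For the infection times, the splits are too few for a share under 0.05: all 10 of 10 gave at least the real count of 0, and the highest other gave 3.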

How the results depend on the processing

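The common floor, the equal number of transcripts, the detection covariate and the paired omission of libraries were chosen after seeing the data. Counts are given for symbiotic cells against aposymbiotic cells of symbiotic larvae (1173), against cells of aposymbiotic larvae (101), and for the aposymbiotic groups (8), in that order where 3 are listed. None of the named transcripts reversed its direction under any setting that gave it a value, but each lost its call under some. Median-of-ratios scaling gave 395, 53 and 4, quantile normalisation 27, 0 and 2, an exact rank-sum test 0, 0 and 0, cell number as a covariate 0, 0 and 4, and log2 transcripts detected as a covariate 0, 0 and 2. With these covariates the median log2 fold of the lower transcripts not listed at 0 in all symbiotic cell libraries was -4.55 and -3.34 (-4.95 without) for 764 in the first comparison, and -6.25 and -5.28 (-6.11 without) for 68 in the second. Their median SE rose from 1.48 to 2.39 and 2.74, and from 1.48 to 2.36 and 2.23; the median of all tested transcripts in the first moved from -2.16 to -1.81 and -0.43. An equal number of transcripts per library gave 4, 0 and 0 (all 4 higher, the abundant transcripts of symbiotic cells, with folds raised by the rescaling), and a common floor of 100 gave 8 (4 higher, 4 lower), 0 and 0. A pseudocount of 5 gave 574 and 23, a pseudocount of 0.1 gave 193 for the second, and no filter gave 404 and 37, with 23052 transcripts tested. Requiring a mean of at least 10 gave 2 for the third. The compared groups alone gave 0 for the second and 1, the lower XM_021059980.1 (adjusted p = 0.0124), for the third. Weights per library gave 3048 for the first; without trend and robust moderation the second gave 302 and the third 36. Without the sample labelled 8 days the first gave 587, and without both the library with the most and the one with the fewest transcripts 93. The cause was not tested, except that fewer samples enter where libraries are left out. For values without ties, a call by the rank test in the first comparison needs 778 transcripts without overlap, where 586 were found. Transcripts tied at 0 in all symbiotic cell libraries can reach a smaller p, so fewer of these could give a call. Leaving out 1 library at a time gave 241 (without replicate 3 of the aposymbiotic cells of symbiotic larvae) to 1508 for the first, also 457, 587, 645 and 767 without symbiotic cell replicates 2 and 4, aposymbiotic replicate 4 and symbiotic cell replicate 3; 9 to 142 for the second; and 0 to 19 for the third. For infection time the range was 0 to 5, with 5 only without symbiotic cell replicate 3. Differences in transcripts detected kept their side of the threshold at a value above 0, at 10 or more and with any library left out. The 70 shared lower transcripts became 0 at an adjusted p under 0.01, which the smallest adjusted p of the second comparison (0.0127) fixes. With the replicate number as a block the third count was 2 and no other count moved by over 1.5 times. Pairing by number was weak, as 1 of 15 same-numbered pairs correlated above 0.1 in their deviations (range -0.024 to 0.18). Of the 15, 5 correlated best with their own number: replicate 1 in every pair of groups, and replicates 2 and 3 between the aposymbiotic groups. A batch shared by some numbers therefore stays open. DESeq2 and the alternatives of the gene list tests were not run, for want of counts and of gene names. The unknown read depth limits what a 0 can mean in any library.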

Other observations

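The relation tests below were chosen after the data were seen. Between symbiotic cell libraries, XM_021059980.1 varied with XM_021061100.1 (Pearson r = 0.970, exact permutation p = 0.00139, Spearman rho = 1, p = 0.00278, n = 6, r = 0.751 without the 2 farthest libraries) and with XM_021059882.1 (r = 0.990, p = 0.00694, rho = 0.829, p = 0.0583, r = 0.864 without the 2 farthest), with adjusted p of 0.0139 and 0.0208 over 10 pairs of the 5 higher transcripts. Of the 10 pairs 4 passed; the others were XM_021044193.1 with XM_021061100.1 (r = 0.930, p = 0.00833, adjusted p = 0.0208, rho = 0.886, p = 0.0333, r = 0.820 without the 2 farthest) and XM_021061100.1 with XM_021059882.1 (r = 0.945, p = 0.00833, adjusted p = 0.0208, rho = 0.829, p = 0.0583, r = 0.752 without the 2 farthest). XM_021048621.1 did not follow XM_021059980.1 by this test (r = 0.571, exact permutation p = 0.229, rho = 0.429, p = 0.419, n = 6). XM_021059980.1 exceeded XM_021061100.1 by a mean log2 ratio of 3.46 in symbiotic cells, 3.56 in aposymbiotic cells of symbiotic larvae and 3.74 in aposymbiotic larvae.

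Among all libraries the first principal component held 27.4% of the variance of the log2 values. Its relation to the log2 number of transcripts detected was tested within symbiotic cells and within the 10 aposymbiotic libraries, since these lie apart. It had an r of 0.929 in the 10 aposymbiotic libraries (100000 permutations, p = 0.00021, adjusted p = 0.00042 over the 2 tests, rho = 0.915, p = 0.00058, r = 0.849 without the 2 farthest libraries). In symbiotic cells it did not pass, at r = 0.700 (exact permutation p = 0.118, adjusted p = 0.118, rho = 0.543, p = 0.297, n = 6, r = 0.922 without the 2 farthest). The component and the number detected were computed from the same values. A relation between them is therefore partly built in, and the p-values do not test it as a finding of its own. Libraries of one group did not in general resemble each other more than libraries of different groups. The median correlation across transcripts was 0.39 within aposymbiotic larvae, 0.43 within aposymbiotic cells of symbiotic larvae and 0.32 within symbiotic cells. It was 0.41 between the 2 aposymbiotic groups, 0.34 between aposymbiotic larvae and symbiotic cells, and 0.32 between aposymbiotic and symbiotic cells of symbiotic larvae. The highest, 0.70, joined replicate 3 of aposymbiotic larvae and replicate 3 of the aposymbiotic cells of symbiotic larvae, the libraries of their groups with the most transcripts (9233 and 15019).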
